A study of Mus musculus with 4 samples.

How the data were processed

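RNA from mouse spleen natural killer (NK) cells was sequenced in 4 libraries, 2 from wild-type (WT) mice and 2 from Tcf7 knock-out (KO) mice, each from its own animal, per the labels. Cells were sorted as TCRbeta-negative, NK1.1-, NKp46-, CD11b- and KLRG1-positive. The labels' protocols give 200 ng of total RNA per library, a TruSeq RNA preparation and paired-end reads from a NextSeq instrument. The deposited values are whole-number counts of reads per gene, identified by Entrez gene number, with a gene length beside them, per the file headers. The authors counted with featureCounts on mm10, per the submitters' processing notes, with versions, the aligner and the strand setting not given in the sources used here. The table of the whole series and the files of the single samples held the same counts, and 0 columns of the table were left without a sample. Reads of near-identical genes, such as members of the Ly49 family, the hemoglobin genes and T cell receptor segments, can be split or lost in counting, so their levels are uncertain.

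Of 26611 gene numbers, 25275 (95.0%) were matched to a symbol in a RefSeq table of the mm10 assembly, from which positions were taken. Genes without a symbol held 1.23% of the counts and stayed in the tests. Total counts were 31860505 and 40175537 in the WT libraries and 28254693 and 37384979 in the KO libraries. Levels are given as CPM, counts scaled to the library total, where 1 CPM stands for 28.3 to 40.2 counts. A count of 0 allows a level of up to 0.075 to 0.106 CPM (3 counts), which covers counting error only.

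Genes were kept with edgeR filterByExpr (minimum count 10), which left 12723. The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 (TMM factors, robust fit, genotype as the only term), with Benjamini-Hochberg adjusted p under 0.05 and no fold threshold. Levels are TMM-scaled CPM unless called raw, and fold changes are KO minus WT on the log2 scale with a standard error (SE) taken from the fold change and the F statistic. For ratios of libraries with the same number, 0.1 CPM was added. All tests are two-sided. Because n is 2 per group, an exact permutation of the 4 labels gives no p under 0.333, and the p-values rest on the spread that the models share across genes.

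The 23 gene lists, the rule for naming genes, the main test and most alternatives were fixed before the data were examined. The lists cover granzymes, granule machinery, Ly49 and other NK cell receptors, late and early maturation genes, transcription factors, the Wnt pathway, cytokines, cytokine receptors, trafficking, interferon response, cell cycle, survival, glycolysis, oxidative phosphorylation, handling response, markers of T, B, myeloid, erythroid and other innate lymphoid cells, and sex-linked genes. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists. The naming rule took Tcf7, then the 10 largest rises and falls and the 5 smallest p per direction among genes passing the test with a mean of at least 5 CPM, no overlap of the groups and an official symbol. It also took up to 4 passing members of each list, or else the 2 most highly expressed with values only, and 17 genes fixed by name. Since no gene passed the main test, the rule for the largest changes was also applied to the calls of DESeq2 1.42.0, and list members passing when adjusted over the list alone were named, with some further list members given by their values. These choices were made after the values were seen.

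Alternatives fixed in advance were DESeq2 size factors, library size only, no filter, at least 5 CPM in 2 libraries, DESeq2's Wald test, limma voom, other dispersion options, the replicate number as a block, a 1.5-fold threshold, each library left out in turn, an estimated correlation for camera, and fry. Offsets for gene length and GC content (91.4% of tested genes had a GC value, others took the median) and DESeq2 without each library were added after seeing the data. Over pairs of libraries, the chi-square per degree of freedom was 34.6 to 266, so no library was a copy of another.

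The tests were run first on counts simulated for the comparison of KO with WT over 12723 genes, with 200 changed. edgeR called 3.1% of the genes changed 2-fold, 30.8% of those changed 4-fold and 87.3% of those changed 8-fold, and 14.4% of its calls were unchanged genes. DESeq2 called 10.8%, 73.8% and 90.5% at these sizes, and 29.1% of its calls were unchanged genes. A simulated list of 30 genes shifted by 0.5 on the log2 scale gave a camera p of 2.37e-08. The simulated genes varied independently, and no difference was shared by libraries of the same number. The shares called therefore need not hold for the real libraries, and the list result does not test lists whose members vary together.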

Results

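The series measured gene expression in mature splenic NK cells, innate lymphocytes that kill target cells with granule proteins, from 2 WT and 2 Tcf7 KO mice of the C57BL/6 background. It asks what Tcf7, which encodes the transcription factor Tcf-1, does in these cells. The sort selected cells bearing CD11b and KLRG1, surface proteins of late NK cell maturation. The libraries held 31860505 and 40175537 counts (WT) and 28254693 and 37384979 counts (KO).

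Tcf7 (Entrez gene 21414; mm10 chromosome 11, 52246527 to 52283383) stood at 89.5 and 79.1 CPM in the WT libraries and at 11.2 and 25.1 CPM in the KO libraries. The raw counts were 2908 and 3106 against 328 and 903. The mean was 84.3 ± 7.35 CPM in WT and 18.1 ± 9.80 CPM in KO (SD, n = 2 each). The log2 fold change was -2.22 (SE 0.45), with an edgeR unadjusted p of 0.00607 and an adjusted p of 1.00 over all genes, and a DESeq2 adjusted p of 0.00216. Both KO libraries lay below both WT libraries. Counts are summed over the gene and do not show which exons the remaining reads came from. Without KO library 2 the log2 fold change was -2.88 and the edgeR adjusted p was 0.00409.

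Among genes with the largest differences, the annexin gene Anxa8 stood at 12.9 ± 1.36 CPM in WT and 191 ± 58.7 CPM in KO cells, and the receptor gene Adgrg5 at 11.9 ± 1.90 and 0.365 ± 0.0335 CPM (SD, n = 2 each). Trim16, which encodes an E3 ubiquitin ligase family member, was counted 4 and 14 times in the WT libraries and 1160 and 2767 times in the KO libraries. Lower in KO cells were the adhesion receptor gene Adgrl4 (log2 fold change -3.17), the glycosyltransferase gene Galnt10 (-2.88), the securin gene Pttg1 (-2.52), the stem cell factor receptor gene Kit (-2.55), the inhibitory receptor gene Klrc1 (-2.02), the co-stimulator gene Icos (-1.79), the syndecan gene Sdc4 (-1.64) and the Ly49 receptor gene Klra1 (-3.65). Higher were Klra5 (2.77), the laminin gene Lamb1 (4.93), the neutrophil granule gene Lcn2 (4.85), the troponin gene Tnni1 (4.23), Trac (3.20), Frmd5 (2.91), Bhlhe41 (2.83) and a T cell receptor variable segment, Trav14d-1.

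These genes were named from the DESeq2 calls after the values were seen. When tested on simulated counts, 29.1% of DESeq2's calls were unchanged genes. The simulated counts held no difference between library numbers, so this share is not an estimate for the real calls. In the main fit genotype was the only term. A difference between library numbers therefore counts as spread within each genotype, which can lower the counts of genes given here. A count of 0, or one below that expected by chance, does not show that the genotypes are alike. Both the adjusted and the unadjusted count were higher with the number as a block, given with the processing choices below. edgeR's quasi-likelihood test called 0 of 12723 genes at an adjusted p under 0.05 (smallest adjusted p 0.561). There were 361 genes at an unadjusted p under 0.05 (216 higher, 145 lower), where 636 would be expected by chance. That unadjusted count was 861 without KO library 2 and 190 without WT library 2, where 661 would be expected in each. DESeq2 called 71 genes, 48 higher and 23 lower in KO, and limma voom called 0. All 71 had both KO libraries on the same side of both WT libraries, which a call with 2 libraries per group nearly requires. Of tested genes 21.2% had this, where 4 exchangeable libraries give 33.3%. The libraries also parted by number and were not exchangeable, so the 33.3% is not a reference for these data. The edgeR count was 35 with no filter on low counts, 33 without KO library 1 and 53 without KO library 2, and the DESeq2 count was 34 without WT library 2. Within libraries of the same number, the log2 ratio of KO to WT was 4.06 and 3.64 for Anxa8, -4.59 and -4.77 for Adgrg5, 7.47 and 7.40 for Trim16, -2.30 and -3.50 for Galnt10, and -2.99 and -1.66 for Tcf7.

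**Figure D1:**
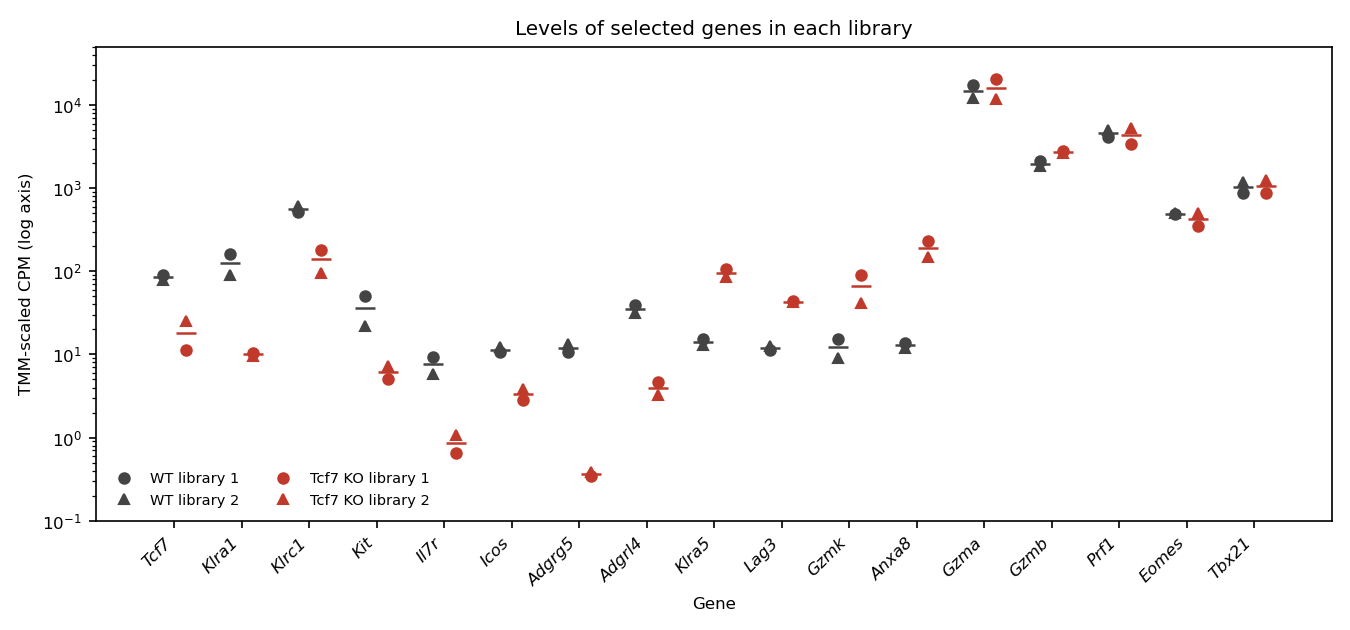
TMM-scaled CPM on a log axis for 17 genes in each library, WT in grey and Tcf7 KO in red, with circles for library 1, triangles for library 2 and short lines for group means. Klra1 lies at 162 and 90.0 CPM in WT and at 10.5 and 9.65 CPM in KO, while Gzma, Prf1, Eomes and Tbx21 overlap between the groups.

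The Ly49 receptors, which bind class I MHC molecules and tune NK cell activity, differed in opposite directions. Klra5 (chromosome 6, 129898988 to 129913237) rose from 14.0 ± 1.68 to 95.7 ± 13.7 CPM, 6.82-fold, and Klra1 (chromosome 6, 130363918 to 130386874) fell from 126 ± 51.0 to 10.1 ± 0.576 CPM (SD, n = 2 each). Both passed when edgeR p-values were adjusted over the list alone (adjusted p = 0.00248 and 0.00251) and none of the 13 tested members passed in edgeR over all genes, while DESeq2 called Klra5 (adjusted p = 4.10e-13) and Klra1 (1.72e-13) over all genes. Klra4 stood at 1274 and 603 CPM in WT and 458 and 211 CPM in KO (log2 fold change -1.49, SE 0.56, edgeR adjusted p over the list alone = 0.162). Klra7 (log2 fold change 1.09, SE 0.55), Klra8 (0.67, SE 0.50) and Klra9 (0.29, SE 0.30) did not pass either. In libraries of the same number the log2 ratio was 2.78 and 2.73 for Klra5, -3.94 and -3.21 for Klra1, -1.48 and -1.51 for Klra4, and 1.09 and 1.07 for Klra7. As a list the receptors were not called in one direction (camera adjusted p = 0.946, direction up, with a median of 0.16 and a mean of -0.01), while fry's test for change in either direction gave an adjusted p of 0.0110. Reads can be shared among the near-identical genes of this family.

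Of 34 other NK cell receptors and adaptors tested, Lag3, an inhibitory receptor gene, rose from 11.9 ± 0.939 to 43.2 ± 0.981 CPM (SD, n = 2 each). It passed when adjusted over the list alone (edgeR adjusted p = 0.0203), the only member to do so, and none passed in edgeR over all genes. DESeq2 called Lag3 (adjusted p = 1.92e-06) and Klrc1 (0.00191) over all genes. The edgeR call of Lag3 was lost without WT library 1 (edgeR adjusted p = 0.177) or WT library 2 (0.0884). Klrc1 stood at 517 and 610 CPM in WT and 183 and 95.7 CPM in KO (edgeR adjusted p over the list alone = 0.0767). The Klri1 and Klri2 receptor genes had log2 fold changes of -1.19 and -0.86. Ncr1 and Klrb1c, which encode the sorted proteins NKp46 and NK1.1 and were the most highly expressed members, differed by -0.08 and -0.01 on the log2 scale, and Klrg1 by 0.58 (SE 0.28). The list as a whole was not called (camera adjusted p = 0.677, direction down, with a median of 0.00 and a mean of -0.17).

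Granzyme and perforin transcripts, the main cytotoxic cargo, did not pass in edgeR over all genes or over the list alone. Gzma stood at 17540 and 12330 CPM in WT and 20480 and 11890 CPM in KO, Gzmb at 2116 and 1842 against 2799 and 2688 CPM (log2 fold change 0.47, SE 0.21), and Prf1 at 4128 and 4999 against 3440 and 5321 CPM. Gzmk stood at 15.1 and 9.17 CPM in WT and 90.2 and 42.1 CPM in KO. It was called higher by DESeq2 (adjusted p = 0.00113) but not by edgeR adjusted over the list alone (0.0512). Gzmc was near 5.54, 1.86, 3.96 and 2.05 CPM in the 4 libraries, and Ifng differed by 0.30 on the log2 scale (SE 0.25). The granzyme list (camera adjusted p = 0.210, direction up, with a median member at -0.23 and a mean of 0.15) and the 18 genes of granule machinery and death ligands (0.399; Nkg7 at -0.10) were not called. Over the 4 members with at least 5 CPM in 2 libraries the granzyme list was called up (camera adjusted p = 0.00980). Its median KO minus WT difference was -0.36 between the libraries numbered 1 and 0.55 between those numbered 2. The direction turned with the library left out, up without WT library 1 or KO library 2 and down without WT library 2 or KO library 1. Fits with a library left out are unbalanced for the library number.

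Early-maturation NK cell genes lay lower in KO cells as a list, with 18 of 27 members below 0 and a median of -0.20 (camera adjusted p = 0.0282). With an estimated correlation the adjusted p was 0.983, and the call was lost without WT library 1 (adjusted p = 0.273) or KO library 2 (0.547). No member passed in edgeR over all genes or when adjusted over the list alone, where the smallest edgeR adjusted p was 0.0524, for Il7r. Il7r, the interleukin 7 receptor gene, fell from 7.59 ± 2.53 to 0.865 ± 0.307 CPM (SD, n = 2 each) when adjusted over the list of other innate lymphoid cell markers alone (edgeR adjusted p = 0.0155), and lost that call without WT library 1 (0.0734). Kit stood at 50.3 and 21.9 CPM in WT and 5.11 and 7.21 CPM in KO. DESeq2 called Kit (adjusted p = 7.92e-04) and Il7r (1.68e-05) lower over all genes. The highly expressed member Cd7 (0.03) and the fixed genes Cd27 (-0.15), Id3 (0.53, SE 0.77) and Lef1 (-0.26) did not pass. The late-maturation list was not called (camera adjusted p = 0.0958), with Itgam at -0.19 and Itgax at 0.78. Itgam and another member, Klrg1, encode the sorted proteins CD11b and KLRG1. Only cells bearing both proteins were sequenced, so neither maturation list shows whether maturation differs among all NK cells.

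Transcription factors of NK and other lymphoid cells also lay lower as a list, 31 of 41 below 0 with a median of -0.15 (camera adjusted p = 0.0282), and the adjusted p was 0.983 with an estimated correlation. The call was lost with no filter on low counts (adjusted p = 0.0557), with offsets for gene length and GC content (0.115) and without WT library 2 (0.964), and turned to the opposite direction, not called, without KO library 1 (0.534). The list's median KO minus WT difference was -0.34 between the libraries numbered 1, with 6 of 41 higher in KO. Between those numbered 2 it was -0.06, with 16 higher. None of the 41 passed in edgeR over all genes or over the list alone. Eomes stood at 488 and 500 CPM in WT and 354 and 508 CPM in KO (log2 fold change -0.20, SE 0.25), and Tbx21, which encodes T-bet, at 869 and 1172 against 868 and 1243 CPM (0.05, SE 0.29). The most highly expressed members were Id2 (-0.20) and Klf2 (-0.06).

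Cell cycle genes lay higher in KO cells as a list, with 33 of 36 members above 0, a median log2 fold change of 0.97 and a camera adjusted p of 5.74e-20. The adjusted p was 0.802 with an estimated correlation. No member passed in edgeR over all genes or over the list alone, and 15 had an unadjusted p under 0.05, all higher. DESeq2 called 1 member over all genes, Ccnb2 (adjusted p = 0.00451). Members chosen after their values were seen were Top2a (7.35 and 12.6 CPM in WT, 20.5 and 21.3 CPM in KO), Ccnb2 (2.03 and 0.993 against 14.1 and 6.13 CPM) and E2f2 (log2 fold change 0.93, SE 0.23). The most highly expressed members, Mcm6 and Mcm4, which serve DNA replication, had log2 fold changes of 0.10 and -0.04. The median was 0.99 between the libraries numbered 1 and 0.77 between those numbered 2. Erythroid and platelet markers (median 1.84) and myeloid and dendritic markers (median 0.86) lay higher in the same KO libraries.

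Of 14 erythroid and platelet markers, 12 were above 0 (median 1.84, camera adjusted p = 1.48e-09; 0.983 with an estimated correlation). Hba-a2 rose from 13.3 and 10.9 to 70.1 and 53.5 CPM, and Hba-a1, Hbb-b1, Hbb-bs and Alas2 also passed when adjusted over the list alone (edgeR adjusted p = 0.00825 to 0.0334). Car2, the most highly expressed member, differed by -0.11. The Hbb-bs call was lost without WT library 2 (0.0694), and that of Alas2 without WT library 1 (0.0933), WT library 2 (0.118) or KO library 1 (0.109) and with voom (0.0553). DESeq2 called Hba-a2, Hba-a1, Hbb-b1 and Hbb-bs over all genes (adjusted p = 6.37e-08 to 0.00451), but not Alas2 (0.0884). All 25 myeloid and dendritic markers tested were above 0 (median 0.86, camera adjusted p = 1.32e-06; 0.983 with an estimated correlation), but none passed in edgeR over the list alone. This call was lost without KO library 1 (adjusted p = 0.881), and the median was 1.2 between the libraries numbered 1 and 0.17 between those numbered 2. For the erythroid list these medians were 2.26 and 1.06. Of the myeloid and dendritic markers, DESeq2 called 2 over all genes, Mpo (adjusted p = 1.08e-05) and Elane (6.65e-04). Elane stood at 0.0615 and 0 CPM in WT and 6.24 and 0.915 CPM in KO. S100a8 stood at 9.94 and 0.687 CPM in WT and 118 and 22.4 CPM in KO, S100a9 at 10.5 and 0.535 against 122 and 22.3 CPM, Mpo at 0.246 and 0.0255 against 11.3 and 2.97 CPM, and Lyz2 at 92.7 and 3.31 against 258 and 18.6 CPM.

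**Figure D2:**
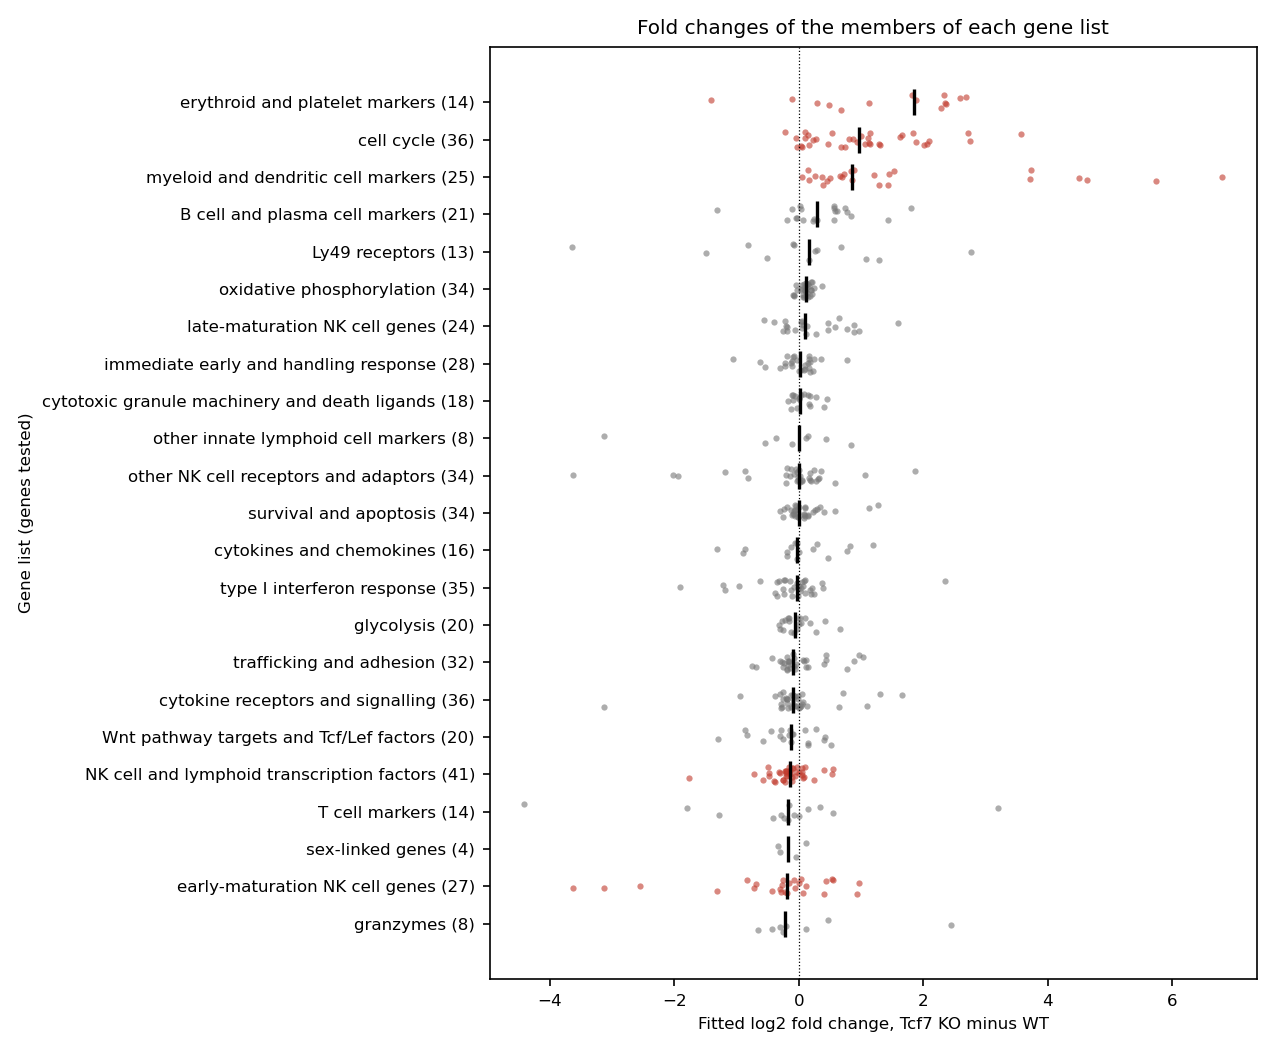
Fitted log2 fold change, KO minus WT, of each tested member of the 23 lists, 1 point per gene, with the list's median as a black line and the number of genes tested in brackets. Red marks the 5 lists called by camera at an adjusted p under 0.05, among them cell cycle (median 0.97) and erythroid and platelet markers (median 1.84), and 0 lists were called with an estimated correlation.

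Among 14 T cell markers tested, Trac, the constant segment of the T cell receptor alpha chain, rose from 5.88 and 8.30 to 94.0 and 36.1 CPM. Icos fell from 10.6 and 12.4 to 2.80 and 3.80 CPM and Trgc4, a gamma chain constant segment, from 3.75 and 1.68 to 0.171 and 0.0832 CPM. All 3 had an edgeR adjusted p of 0.0167 over the list alone, and all 3 lost it without WT library 1 (0.0594), Icos also without WT library 2 (0.0938). DESeq2 called Trac (adjusted p = 7.04e-06), Icos (0.00377) and Trgc4 (3.50e-04) over all genes. Cd28 stood at 88.9 and 64.7 CPM in WT and 39.9 and 23.1 CPM in KO and did not pass. Trbc2 (log2 fold change -0.24) and Trdc (-0.08), the most highly expressed members, did not pass either. Trav14d-1 was counted 0 times in both WT libraries and 515 and 176 times in the KO libraries, at least 50-fold higher against a floor of 3 counts per library. The T cell list was not called as a whole (camera adjusted p = 0.287). It was called down without WT library 2 (adjusted p = 4.07e-07) or KO library 1 (0.00712). B cell and plasma cell markers (0.487; Igkc at 1.80, SE 0.92, and Ighm at 0.30), other innate lymphoid cell markers (0.434, direction down, with a median of 0.00 and a mean of -0.33; Itga1 at 0.44 and Tnfsf10 at -0.11) and sex-linked genes (0.487; Eif2s3y at -0.34 and Ddx3y at 0.12) were not called. The direction of the B cell list turned with the library left out, called up without WT library 1 (adjusted p = 0.0208) or KO library 2 (4.30e-06) and down without KO library 1 (5.19e-05). The other innate lymphoid cell list was called down without WT library 1 (adjusted p = 0.0362).

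The remaining lists were not called by camera, and no member passed in edgeR when adjusted over its list alone. Adjusted p-values were 0.279 for Wnt pathway targets and Tcf/Lef factors (Ctnnb1 at 0.10, Cd44 at -0.30), 0.945 for cytokines and chemokines (Ccl5 at -0.03, Il16 at -0.19) and 0.287 for cytokine receptors and signalling (Il2rb at -0.09, Jak1 at -0.29). They were 0.945 for trafficking and adhesion (Itgb2 at -0.19, Itgal at -0.24), 0.399 for the type I interferon response (Ifi47 at 0.22), 0.434 for survival and apoptosis (Gimap4 at -0.08, Gimap3 at -0.09) and 0.861 for glycolysis (Pkm at -0.13, Ldha at 0.27). The direction of the test differed in sign from the median for cytokines (up, -0.03) and the handling response (down, 0.02), and from the mean for trafficking (down, 0.03). Oxidative phosphorylation gave 0.160 (Atp5a1 at 0.12, Atp5b at 0.11) and the immediate early and handling response 0.945 (Jund at -0.11, Btg2 at -0.10). Several of these were called under other settings, among which the fits with a library left out are unbalanced for the library number. Without WT library 1 and KO library 2 respectively, the Wnt list was called down (adjusted p = 0.0147 and 0.0152) and oxidative phosphorylation up (0.00357 and 0.00113). Oxidative phosphorylation was also called up among genes with at least 5 CPM in 2 libraries (0.0335). The interferon list was called down without WT library 2 (0.0346), cytokine receptors down without KO library 2 (0.0441), and the handling response up without KO library 1 (0.0136) but down without KO library 2 (0.00961).

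The 4 libraries parted more by their number than by genotype. The first principal component of log2 CPM held 64.9% of the variance and separated the libraries numbered 1 from those numbered 2 in both genotypes, and the second held 26.0% and separated KO from WT. Over 5 groups of tested genes ordered by length, the median difference of library 2 from library 1 ran from -0.31 to 0.48 in WT and from -0.47 to 0.65 in KO, while the mean KO minus mean WT difference ran from 0.07 to -0.10. Myeloid markers lay lower in the libraries numbered 2 (median -1.58 in WT and -2.19 in KO), as did granzymes (-1.27 and -1.01), B cell markers (-0.76 and -1.73) and Ly49 receptors (-0.76 and -0.95). Wnt pathway genes (0.67 and 0.82) and transcription factors (0.51 and 0.68) lay higher in them. A fit with a library left out is unbalanced for the number, so part of these differences enters its KO minus WT values. edgeR called 2512 genes between the numbers with the number as the only term, and 0 between the genotypes with genotype as the only term. In the genotype fit the difference between the numbers counts as spread within each genotype. A fit with the number as a block is given with the other processing choices below. The labels give no batch or date for these numbers.

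**Figure D3:**
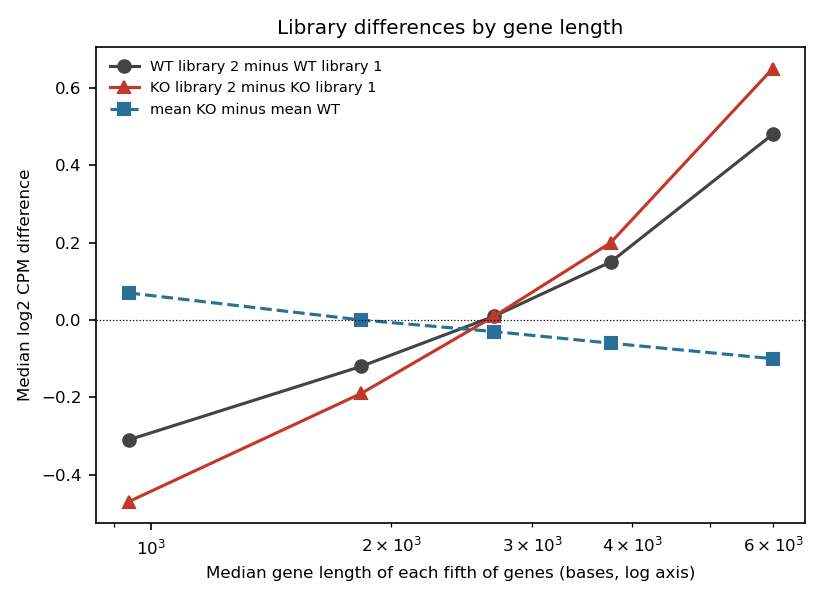
Median log2 CPM difference (vertical axis) of genes in 5 groups of near-equal size ordered by gene length in bases (horizontal log axis), for library 2 minus library 1 of each genotype and for mean KO minus mean WT. The median for the group of longest genes is 0.48 in WT, 0.65 in KO and -0.10 for KO minus WT.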

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

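The fits with offsets for gene length and GC content, and the DESeq2 fits without each library, were chosen after seeing the data. The count of genes stayed at 0 with DESeq2 size factors, library size only, at least 5 CPM in 2 libraries, limma voom, the other dispersion options, a 1.5-fold threshold and the length and GC offsets. It was 35 with no filter on low counts and 71 with DESeq2, which shared 35 calls. Leaving out each library gave 0 to 53 genes with edgeR, and 34 to 74 with DESeq2. A group left with 1 library is assumed to vary like the other. With the replicate number as a block (replicate block) edgeR called 221 genes, 67 of them shared with DESeq2, and with the block and the offsets together 243. Under the block, 1373 genes had an unadjusted edgeR p under 0.05, where 636 would be expected by chance. The numbers are not stated to pair the mice. Deviations from the group mean correlated at 0.73 across genes between libraries of the same number. The Tcf7 log2 fold change ran from -2.88 to -1.75 over all alternatives and its adjusted p from 0.00216 to 1. It passed with no filter (-2.21), with DESeq2 (-2.20) and without KO library 2 (-2.88). It did not pass under the block (-2.31). The number of lists called was 5, 0 with an estimated correlation, 0 with fry in one direction, 4 with no filter or with the offsets, 7 with at least 5 CPM in 2 libraries, and 6 to 10 with a library left out. Camera does not use the DESeq2 test or edgeR's dispersion options, so those alternatives gave no list value. Cell cycle and erythroid calls held in 11 of 13 alternatives, myeloid in 10, early maturation in 8 and transcription factors in 7. Under the block, early maturation was not called (adjusted p = 0.0702) and oxidative phosphorylation was called up (0.0431), and no other list gained or lost its call. Without KO library 1, the transcription factor list turned up (adjusted p = 0.534), as did the handling response (0.0136), and B cell markers turned down (5.19e-05). With each library left out, the adjusted p ran from 6.72e-05 to 0.964 for transcription factors, from 0.00961 to 0.661 for the handling response and from 4.30e-06 to 0.408 for B cell markers. Apart from the smaller number of libraries, these fits are unbalanced for the replicate number, so part of the difference between numbers enters KO minus WT. The median of number 2 minus number 1 was 0.51 in WT and 0.68 in KO for transcription factors. It was 0.24 and 0.82 for the handling response and -0.76 and -1.73 for B cell markers. The turns without KO library 1 have the signs of these medians. How much of the turns this accounts for was not tested. Of 99 named genes other than Tcf7, 64 had the same sign in every alternative, as had 1410 of 1473 single values. Depth limits genes at 0 in both WT libraries, for which only a bound can be given.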

Other observations

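The tests on T cell receptor transcripts and on the neighbourhood of Tcf7 were chosen only after the result was seen. Those on the libraries' numbers had their bounds written down before the result of each was seen, but the test of gene length and GC content as the whole of the split was added after the share of variance they give was known.

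Other genes outside the naming rule, chosen after their values were seen, were called higher in KO cells by DESeq2. The apoptosis gene Pmaip1 stood at 13.9 and 12.1 CPM in WT and 28.4 and 34.3 CPM in KO (adjusted p = 0.0318), and the interferon-inducible gene Xaf1 at 19.1 and 20.9 against 71.3 and 132 CPM (adjusted p = 2.57e-05). Neither passed in edgeR when adjusted over its list alone (0.139 and 0.0777).

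The libraries numbered 1 and 2 stood apart in both genotypes. Sequencing depth alone does not account for it, since the first component still held 64.7% of the variance and still parted the numbers after all libraries were thinned to 28254693 counts. Gene length and GC content together gave 31.2% of the variance of the difference across genes, between the bounds set for most of it and for little of it, so the size of their part cannot be told apart from other sources. As the whole of the split they are argued against, since 1320 genes were called between numbers with offsets for both, a count 52.5% as large as the 2512 without them and close to the bound of 50% set in advance, and the difference in WT still correlated at 0.63 with that in KO across genes. No biological explanation was tested, because the labels name no difference between the numbers.

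T cell receptor alpha transcripts were higher in both KO libraries, with Trac counted 191 and 326 times in WT and 2756 and 1300 times in KO. Of 51 J segments, 1 (Traj33, 135 and 64 counts) had at least 5 counts in both KO libraries and 0 in both WT libraries, and the 4 V segments that did so (of 116) all belonged to family 14. This rule leaves out segments with any WT read, such as Trav14-1 (5 and 3 counts in WT, 35 and 16 in KO). It can therefore miss other segments that rose. T cells among the sorted cells are argued against, since 9 other T cell genes tested, of 10 listed, had a median log2 fold change of -0.16 (highest 0.55) and raw CPM in the KO libraries were 0.248 and 0.589 for Cd3e, 3.26 and 1.2 for Cd3d and 5.63 and 3.21 for Cd3g, against 97.5 and 34.8 for Trac, and the sort removed TCRbeta-positive cells. A hypothesis that these values leave open is that both KO mice may carry 1 rearranged T cell receptor alpha gene, which the labels do not mention. An effect of Tcf7 loss on the locus was not tested, and reads are shared among the near-identical copies of these segments.

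Genes called by DESeq2 lay near Tcf7 on chromosome 11. Within 20 Mb of it, 5 of 298 tested genes were called, 2 higher (Trim16 and Trim58) and 3 lower (Pttg1, Galnt10 and 2610507I01Rik). Elsewhere 60 of 12116 were called (odds ratio 3.43, 95% interval 1.07 to 8.54, Fisher's exact p = 0.0197). Tcf7, hemoglobin genes and genes without a known position on an autosome or the X chromosome were left out. Xaf1, also called by DESeq2, lies just outside this window (chromosome 11, 72301461 to 72313733). A passenger chromosome segment from another strain around the targeted allele may account for such a cluster, as a hypothesis. Chance clustering also stays open. Of 476 other 40 Mb windows, 6.7% held as high a share of called genes, those with the T cell receptor alpha genes included. These windows were set every 5 Mb, so they overlap, and each needed only 50 tested genes. The 6.7% is therefore not a chance rate. An effect of Tcf7 loss on these genes follows the same groups and was not tested.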
